A study of Drosophila melanogaster with 4 samples.

How the data were processed

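The series holds 4 samples of Drosophila melanogaster S2-DRSC cells, a male line derived from late embryos. All were treated with double-stranded RNA against H2Av, the fly histone H2A variant. Per the labels, cells received 50 µg of the double-stranded RNA, grew for about 4 days, and were treated again with 200 µg before fixation with formaldehyde. Chromatin was immunoprecipitated with a rabbit polyclonal antibody to an H2Av peptide (number 9751) and sequenced as 2 ChIP replicates, beside 2 input DNA samples. Samples were grouped by their titles. The description of ChIP replicate 2 reads as input, and that of input replicate 1 names both kinds of DNA, so titles and source names, which state the kind of DNA in each sample, were followed.

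The values analysed were 3 lists of enrichment clusters, which are genomic regions called by the authors. There was 1 list for each ChIP replicate and 1 for the replicate set, whose regions were given as one result for both. Positions follow FlyBase release 5 per the file headers. Each region carries a score deposited by the authors. Bowtie 0.12.7 is named in the submitters' processing notes. The caller, its threshold, the formula of the score and the use of the inputs in it are not given in the sources used here. Start positions in the replicate-set list were all even and its narrowest region was 1001 bp, against 1301 bp in both replicate lists, so the replicate-set list differs from the others in more than the reads behind it.

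The scale of the score was examined on values that recurred at least 3 times in a list. Differences between such values were compared with base-2 logarithms of ratios of whole numbers up to 20, at a relative tolerance of 1e-06. Matches numbered 80 of 1081 pairs in replicate 1, 131 of 1275 in replicate 2 and 152 of 1711 in the replicate set. Equal numbers of non-recurring scores gave 1, 0 and 0 matches, natural logarithms gave 0 in each list, and base-10 logarithms gave 2, 3 and 4. Scores were therefore read as differing on a log2-like scale. They were used to rank and describe regions within a list, and score differences below are in score units.

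From the replicate-set list, 1 region marked as depleted (3L, 3417396 to 3419158) was left out. Regions ending past the sequence length in the header (2 in each replicate list and 3 in the replicate set) were ended at that length. Read depth is unknown because the lists hold no counts, so no counting interval can be given, and weak regions may be absent from a list for lack of reads. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. Values of the input samples were not analysed here. Cells without the double-stranded RNA were not analysed here, and the H2Av level after treatment was not measured here.

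Overlap was counted from 1 shared bp. The mean of the 2 shares, 1 from each replicate, was compared with 1000 circular shifts within each chromosome. In each of these, either list was shifted in turn against the other and the 2 shares were averaged. The one-sided permutation p so obtained cannot fall below 0.001. Ratios between parts of the genome were computed per replicate, with 95% intervals from 2000 bootstrap draws of 500 kb windows; those intervals describe variation along the genome, and neighbouring windows are not fully independent. A ratio was called when the intervals of both replicates excluded 1. Values over replicates are means with the SD (n = 2). The arms X, 2L, 2R, 3L and 3R were split into the fifth nearest the centromere (high coordinates on X, 2L and 3L, low coordinates on 2R and 3R) and the rest. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

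The overlap and ratio calculations were tested on simulated data. For the replicate overlap, simulated lists of 4562 regions returned the true share of 69.2%, and 11 of 200 pairs of unrelated lists gave p of 0.05 or below, where 10 are nominal. For the proximal ratio, a simulated ratio of 2 was returned as 2.00 on average, and all 40 intervals held the true value. Simulated regions were placed at random along each chromosome or part, without the uneven spacing of the real lists. How the shifts and intervals perform on unevenly spaced regions was not tested.

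Designs, the alternatives listed next and the rule for named regions were fixed before the data were examined; alternatives added later are named in the closing section. The rule takes the 10 highest-scored replicate-set regions that overlap both replicates, the widest region per chromosome arm and the longest stretch without a region per arm. Alternatives were a reciprocal overlap of 50%, the upper part of each list by score from its median, shifts of 20 to 200 kb, merging within 200 bp, the replicate-set list, the other measure of density (percent covered or regions per Mb) for X, chromosome 4 and heterochromatin, the 10% of each arm nearest the centromere, other pairings, and leaving out each replicate. Comparisons with transcription start sites and with 14 gene lists had also been planned. The gene table at hand follows release 6, so these were not run and no gene is named.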

Results

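H2Av is the histone H2A variant of Drosophila and serves the roles that H2A.Z and H2A.X have in other animals. ChIP-seq with an antibody to an H2Av peptide was run on S2-DRSC cells, a cultured line from late male embryos. The cells had undergone 2 rounds of RNA interference against H2Av itself. The 2 ChIP replicates are described by their lists of enriched regions and by the authors' list for the replicate set. No list for the 2 input samples was analysed here. The labels name the antibody and the double-stranded RNA as the factors of the experiment. Cells with normal H2Av were not analysed here, so every value describes RNAi-treated cells and none measures the effect of the treatment. The H2Av level was not measured and use of the inputs in the score is unknown, so whether the regions mark remaining H2Av was not tested. Below, H2Av-enriched regions, H2Av regions and H2Av cover therefore refer to regions called from ChIP with this antibody.

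Regions enriched in the ChIP with the H2Av antibody were numerous and wide after the RNAi treatment. Replicate 1 had 5019 regions and replicate 2 had 5037, and they covered 25.3 and 24.7 Mb. The median region was 3651 ± 67.9 bp wide (SD, n = 2), and regions above 20 kb numbered 72 in replicate 1 and 64 in replicate 2. On the X, 2L, 2R, 3L and 3R arms they covered 19.3% ± 0.286 of the sequence (SD, n = 2), and the median gap between neighbours was 3978.5 ± 36.1 bp (SD, n = 2). Wider regions carried higher scores, with a Spearman correlation of 0.684 in replicate 1 and 0.687 in replicate 2 across regions, which are not independent replicates.

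The 2 replicates enriched largely the same places. In replicate 1, 4520 of 5019 regions (90.1%) overlapped a region of replicate 2, and in replicate 2, 4612 of 5037 (91.6%) overlapped a region of replicate 1. The mean of these 2 shares was 90.8%. Circular shifts gave a mean of 30.95% for the same measure and never more than 37.7% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The lists shared 22.9 Mb, which is 90.6% of the sequence covered in replicate 1 and 92.7% of that in replicate 2. The 499 regions seen in replicate 1 alone were narrow (median 1571 bp) and weak (median score 0.626), against 3984.5 bp and 1.25 for its shared regions. The 425 regions of replicate 2 alone had a median width of 1551 bp and a median score of 0.608, against 3841.5 bp and 1.28.

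Strongly and weakly enriched regions kept their rank between the replicates. Over 3685 regions that matched one to one, the scores had a Spearman correlation of 0.957 (95% interval 0.952 to 0.961) and a Pearson correlation of 0.955 across regions. The median score difference, replicate 2 minus replicate 1, was 0.04 with an SD of 0.14 across regions. In 100 kb windows along the arms, the percent covered had a Spearman correlation of 0.994 over 1194 windows. Of these, 196 windows (16.4%) held no region in either replicate.

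**Figure D1:**
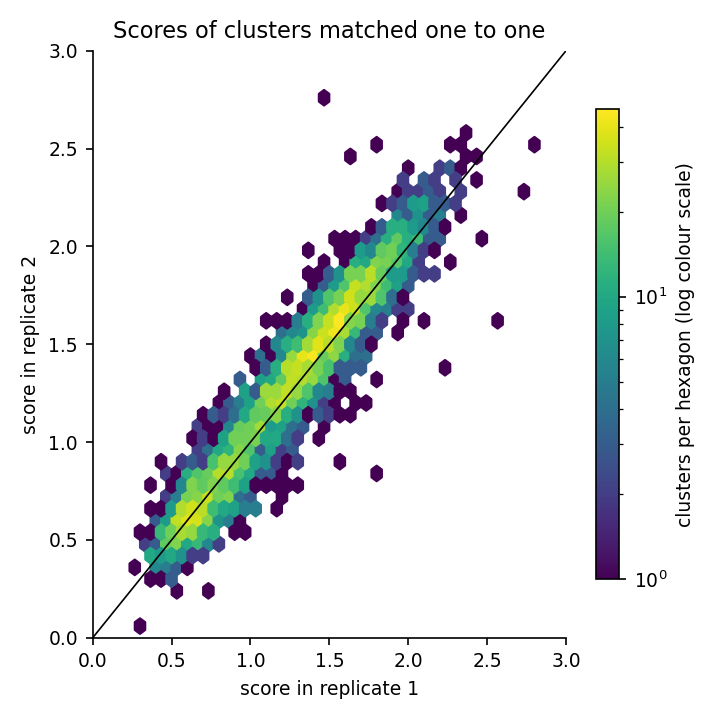
Scores of the 3685 regions matched one to one, replicate 1 on the horizontal axis and replicate 2 on the vertical axis, both in the authors' score units; hexagon colour gives the number of regions on a log colour scale and the line marks equality. Points lie along the line, with a Spearman correlation of 0.957.

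The replicate-set list held 6065 regions and added mainly weak ones. Of these, 3984 (65.7%) overlapped regions of both replicates, 408 (6.73%) of replicate 1 only and 350 (5.77%) of replicate 2 only, while 1323 (21.8%) overlapped neither. The list was given for the same 2 replicates, so overlap with them is built in and no test of it is reported. Regions present in both replicates had a median score of 1.23 and a median width of 5056 bp, against 0.432 and 1940 bp for those in 1 replicate and 0.438 and 1307 bp for those in neither. All but 7 regions of replicate 1 and 5 of replicate 2 overlapped a region of the replicate-set list, which covered 23.5% of the arms.

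**Figure D2:**
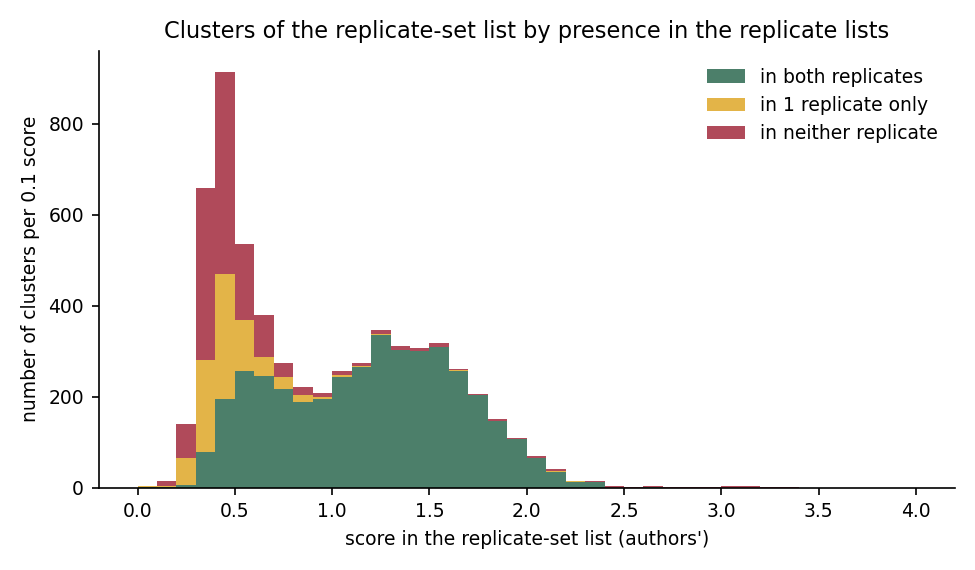
Number of replicate-set regions per 0.1 of the authors' score (vertical axis) along the score (horizontal axis), stacked by presence in both replicates (3984), in 1 replicate only or in neither (1323). Regions in both replicates have a median score of 1.23 and those in neither 0.438.

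The X of these male cells, the dosage-compensated chromosome of flies, was covered by H2Av regions about as much as the autosomal arms. Regions covered 18.4% ± 0.648 of X, 18.9% ± 0.209 of 2L, 23.7% ± 0.328 of 2R, 18.0% ± 0.117 of 3L and 18.3% ± 0.173 of 3R (SD, n = 2 each). The ratio of X to the autosomal arms was 0.941 ± 0.0235 (SD, n = 2). Its 95% interval included 1 in replicate 1 (0.957, 0.817 to 1.12) and in replicate 2 (0.924, 0.789 to 1.08), so no difference was called. Among regions in the upper part of each list by score, the mean ratio was 1.06, on the other side of 1, again with intervals that included 1. Read depth on X and on the autosomes of these male cells is unknown here, so similar cover cannot be read as similar enrichment.

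Chromosome 4, the small repeat-rich autosome, was far more densely covered than any large arm. Regions covered 46.7% ± 1.22 of it (SD, n = 2), and each replicate had 118 regions on it, or 87.3 per Mb. This was 2.27 ± 0.00458 times the density of the arms (SD, n = 2). Scores on chromosome 4 were low, with a mean median of 0.868 against 1.33 on X and 1.14 on 2L, and among regions in the upper part of each list by score the density ratio was 1.14. Chromosome 4 is too short for a bootstrap interval.

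Taken as one group, heterochromatic scaffolds carried fewer H2Av regions per Mb than the arms, with a lower median score. Their density relative to the arms was 0.702 ± 0.0145 (SD, n = 2), with intervals of 0.458 to 0.936 in replicate 1 and 0.468 to 0.974 in replicate 2. XHet (46.5 ± 10.4 per Mb) and 3LHet (42.8 ± 1.94 per Mb; SD, n = 2 each) lay above the arms, which had 38.3 per Mb in replicate 1 and 38.4 in replicate 2. Cover differed between scaffolds: 19.9% ± 2.65 of XHet, 18.1% ± 0.729 of 3LHet, 13.0% ± 0.0527 of 2RHet, 8.15% ± 0.336 of 2LHet, 5.87% ± 0.451 of 3RHet and 2.03% ± 0.354 of YHet (SD, n = 2 each). Unplaced sequence (U) was covered to 2.60% ± 0.0366 (SD, n = 2). Uextra (29.0 Mb) held no region in any list. Density and cover were taken over the full length in the header. How much of each scaffold reads could be mapped to is unknown here, so low values cannot be read as absence of H2Av. The median score on the heterochromatic scaffolds lay below that of the arms in replicate 1 (0.821 against 1.22) and in replicate 2 (0.819 against 1.26). YHet and 2LHet, with 3 to 7 regions per replicate, had higher mean medians of 1.87 and 1.42. The ratio was 0.881 in the replicate-set list with an interval of 0.605 to 1.15, which ends the call, and it was 0.300 among upper-scored regions.

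**Figure D3:**
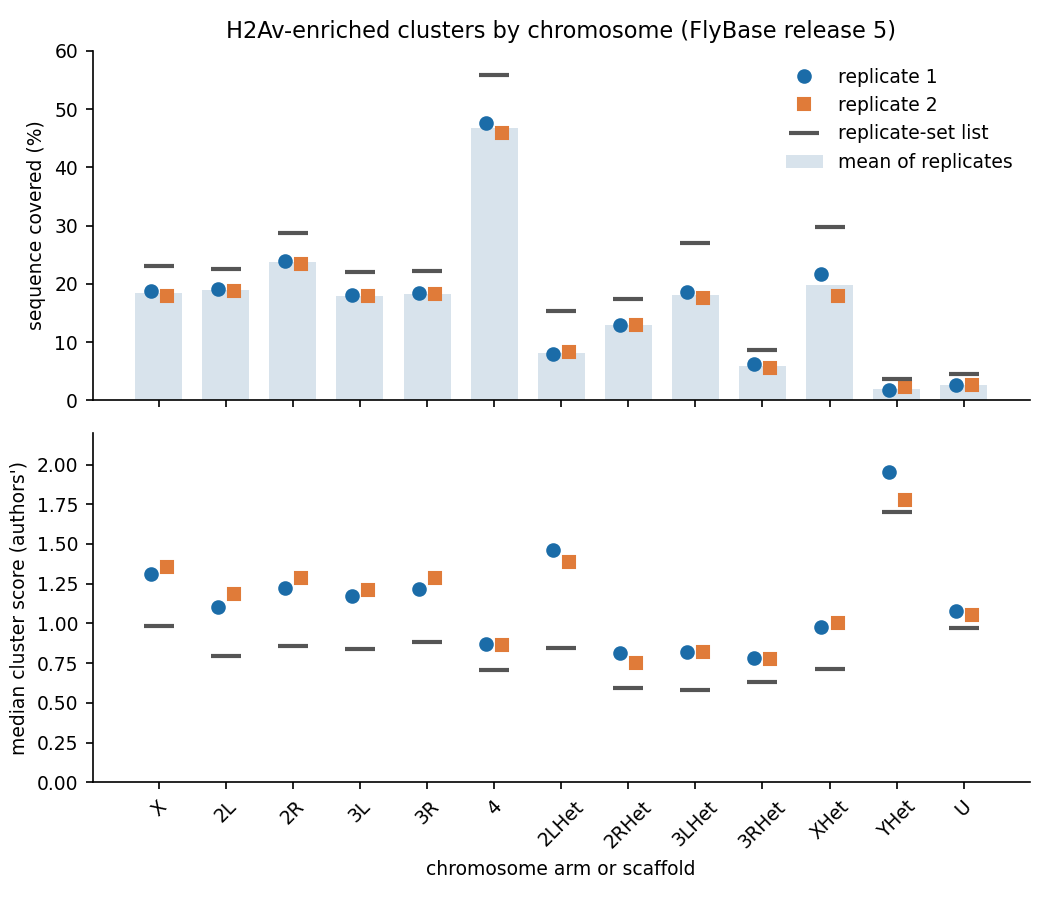
Percent of sequence covered by H2Av-enriched regions (top) and median authors' score (bottom) for each chromosome arm or scaffold; circles and squares are the 2 replicates, bars their mean, and dashes the replicate-set list. Chromosome 4 stands at 46.7% cover with a median score of 0.868.

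The fifth of the arms nearest the centromere was more densely enriched than the rest. It held 1.32 ± 0.00523 times as many regions per Mb (SD, n = 2), with intervals of 1.14 to 1.503 in replicate 1 and 1.14 to 1.52 in replicate 2, and was covered to 25.0% ± 0.253 against 17.9% ± 0.294. Cover was 31.6% against 15.8% on 2L (ratio 2.00 ± 0.0177, SD, n = 2) and 31.8% against 21.7% on 2R (ratio 1.47 ± 0.0153, SD, n = 2), with intervals above 1 in both replicates. The ratios of 1.45 on 3L, 1.24 on 3R and 0.921 on X had intervals that included 1 in both replicates. Among upper-scored regions the density ratio was 1.05, with intervals that included 1. With 2L and 2R both left out, a comparison chosen after the results were seen, it was 1.22 and the interval of replicate 1 (0.993 to 1.44) included 1.

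**Figure D4:**
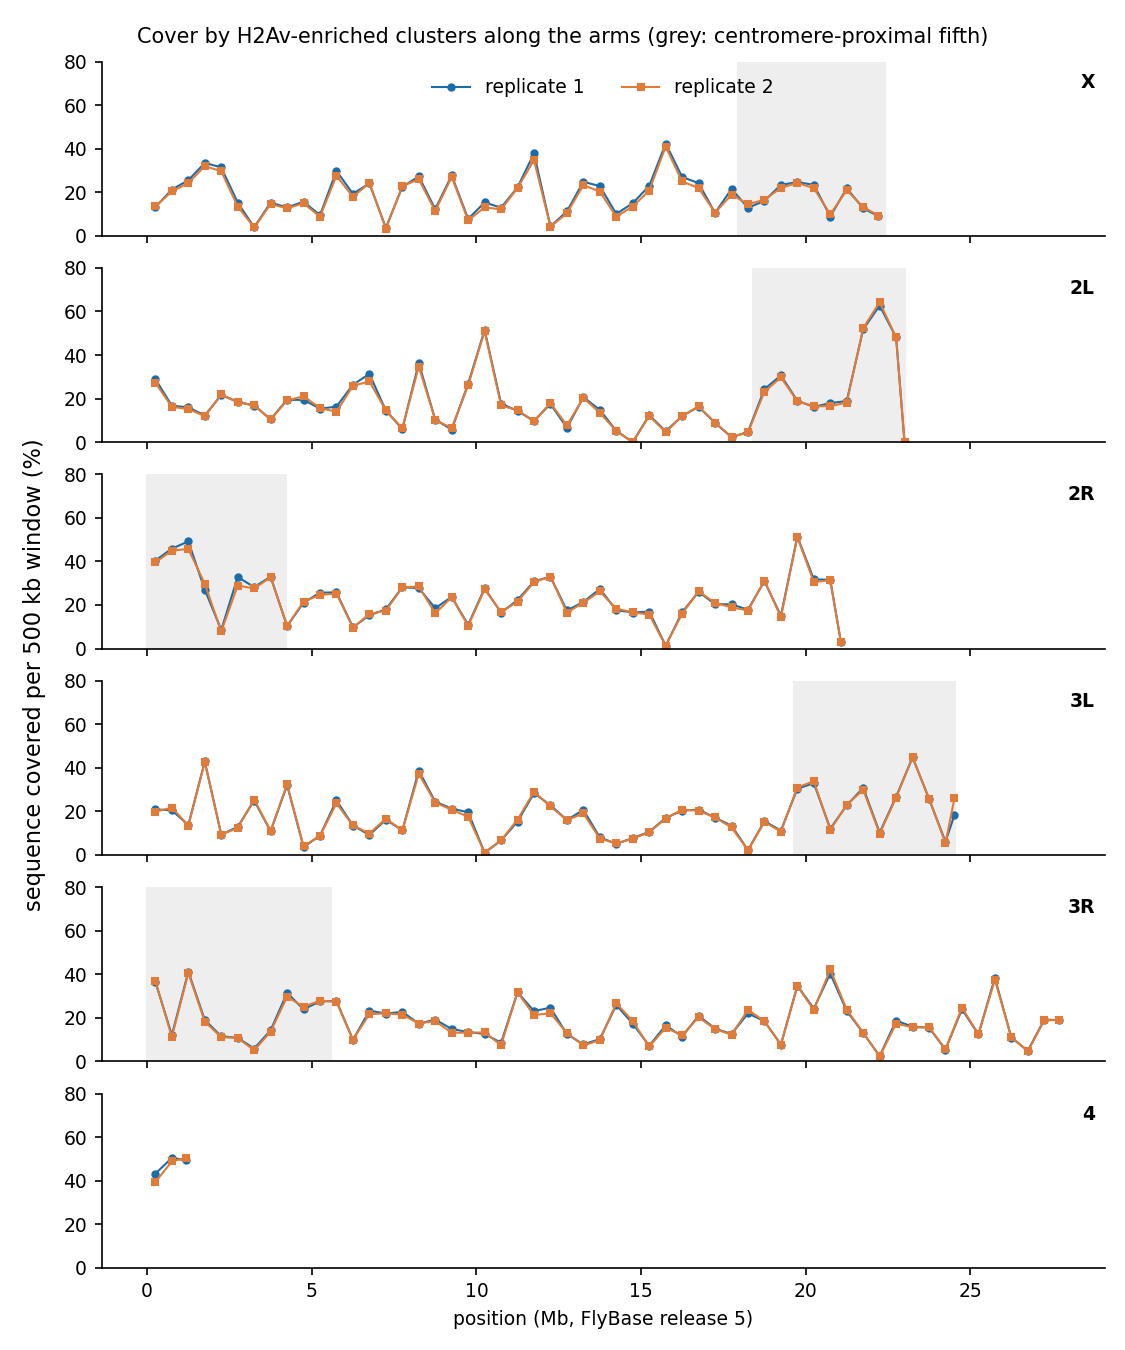
Percent of each 500 kb window covered by H2Av-enriched regions (vertical axis) along X, 2L, 2R, 3L, 3R and 4 in Mb (horizontal axis), with 1 line per replicate and the fifth nearest the centromere in grey; the last window of each arm is shorter. The proximal part is covered to 31.6% on 2L and 31.8% on 2R, and chromosome 4 to 46.7%.

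Of the 10 highest-scored regions of the replicate-set list that overlapped both replicates, 6 lay on X, which held 1017 of all 6065 regions of that list. They were X 1352124 to 1374230 (score 2.40), X 1261218 to 1266152 (2.37), X 819402 to 831134 (2.37), X 17742356 to 17756304 (2.35), X 21474386 to 21496344 (2.32) and X 15220472 to 15231608 (2.31). The others were YHet 327058 to 329258 with the highest score (2.61), 3R 23095108 to 23102542 (2.38), U 4847524 to 4850694 (2.35) and 2L 22792374 to 22795086 (2.35). The U and 2L regions had exactly the same score, 2.35279, and such recurring scores are taken up in the closing section. Scores above all of these belonged to 15 regions found in neither replicate, the highest being 2RHet 2997704 to 2998788 (3.38).

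The widest region of the replicate-set list, 60381 bp, lay in proximal 2L at 22063152 to 22123532, where replicate 1 had 3 regions and replicate 2 had 6. On the other arms the widest were 2R 13607766 to 13650718 (42953 bp), 3R 6671226 to 6712900 (41675 bp), 3L 16569602 to 16610546 (40945 bp) and X 13052106 to 13089576 (37471 bp). Chromosome 4 had one of 40595 bp at 163704 to 204298, and each replicate had 1 region overlapping it.

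Long stretches held no enriched region. The longest were nearly identical in the replicates on 2L, at 14364026 to 15002088 in replicate 1 and 14364558 to 15003286 in replicate 2 (638.1 and 638.7 kb). They were also nearly identical on 2R (563.5 and 563.8 kb, from 15562570 and 15562543) and on 3L (504.6 kb in both, from 18108869 and 18108790). The same held on 3R (369.0 kb in both, from 23790813 and 23790986). The longest stretch on X differed, from 20527619 to 20893300 in replicate 1 and from 7219785 to 7573250 in replicate 2. In the replicate-set list the longest stretch was 561.2 kb on 2R (15562705 to 16123873), while those on 2L (482.5 kb, 15773739 to 16256241) and 3L (375.6 kb, 13519299 to 13894851) lay elsewhere than in the replicates. Those on 3R (344.0 kb, 23815903 to 24159869) and X (345.7 kb, 7226901 to 7572615) lay within the stretches of replicate 2. Whether reads could be mapped in these stretches is unknown here.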

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

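The comparison without 2L and 2R, those leaving out single arms, percent cover of the proximal part, and all those of scores on X were chosen after the results were seen. With 2 replicates, the 18 values that leave out 1 of them could hardly change a call or move beyond the SD, and 2 more concern overlap with the replicate-set list, which is built in; these 20 say nothing about stability. Of the other 37 alternative values, 22 kept their side of the threshold, moved by less than the spread between replicates or, for the number of regions, stayed within 1.5 times; 10 moved by more and 5 lost the call. Among the 22, the number of regions was 4748.5 after merging and 6065 in the replicate set, beyond the replicate SD of 12.7 around 5028. No called result reversed, but the uncalled X ratio passed from 0.941 to 1.06 among upper-scored regions. Merging regions within 200 bp moved the median width to 3775 bp and the median gap to 4458.75 bp. The replicate-set list moved the width to 3521 bp, the gap to 2959 bp, the cover of the arms to 23.5%, the chromosome 4 ratio to 1.87 and the heterochromatic ratio to 0.881, which ended the call. Score agreement was 0.893 over every overlapping pair and 0.950 for width. For chromosome 4 the ratio was 2.41 by percent covered and 1.14 among upper-scored regions. The proximal ratio was 1.05 among upper-scored regions and 1.22 without 2L and 2R, and neither was called. The higher median score on X was 0.0794 above 2R and 0.0821 above 3R, where the interval of replicate 2 included 0. The cause of these changes was not tested. Start-site and gene-list alternatives were not run, for want of a release 5 annotation. No paired analysis was possible because the inputs have no values in the lists. With depth unknown, weak regions present in 1 list only cannot be read as absent from the other replicate.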

Other observations

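All tests below except that of regional copy number and that of the median score among strong X regions were chosen after the results were seen; the latter was added when a first test on X left the question open.

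H2Av cover was uneven along single arms. Each arm was divided into 10 equal parts. On 2L the part nearest the centromere (20710390 to 23011544) was covered to 41.7% ± 0.0810, whereas the part at 13806927 to 16108080 was covered to 6.67% ± 0.173 and the next, 16108081 to 18409235, to 9.11% ± 0.0233 (SD, n = 2 each). On 2R the part nearest the centromere reached 38.5% ± 0.420, and on X the corresponding part 13.9% ± 0.0711 (SD, n = 2 each). Among 86 blocks of the length of chromosome 4 tiled along the arms, 1 block, 2L 21629713 to 22981569, was covered more than chromosome 4, at 56.4% in replicate 1 and 57.4% in replicate 2. The lowest block was 3L 13518571 to 14870427, at 6.22% and 5.99%. Of the 83 windows of 100 kb covered over 50% in both replicates, 34 lay in the fifth nearest the centromere.

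The 15 highest scores of the replicate-set list belonged to regions that neither replicate held, 9 on heterochromatic scaffolds or U and 6 on the arms. Scores this high were not confined to that list. Its maximum was 3.38, against 3.91 in replicate 1 and 3.68 in replicate 2. Among the 100 highest scores of the replicate-set list, 33 regions lay in neither replicate (median width 1041 bp) and 64 in both (7860 bp). The median width of the 33 lay below that of the narrowest region in either replicate list. Regions so narrow were not listed on their own in any replicate, whatever their score. Their absence from the replicates therefore cannot be read as a lack of enrichment there. A score built from few reads is a candidate explanation: 25 of the 33 had a score that recurred exactly in the list, against 2 of the 64, a difference of 72.6 percentage points (95% interval 57.3 to 86.3). Repeat-rich sequence is another: 25 of the 33 lay on heterochromatic scaffolds or U, against 186 of the 1290 lower-scored regions in neither replicate, a difference of 61.3 points (46.0 to 75.3). Both remain open, as does the difference between the lists in narrowest width, and no biological explanation was tested. Location on such scaffolds does not cover the 6 on the arms. Of these, 2L 22573710 to 22574860, 2L 22790464 to 22791466 and 3L 21359252 to 21360270 lay in the fifth nearest the centromere. Those at 3L 5298618 to 5299748, 2L 4540404 to 4541404 and 2L 10862894 to 10863894 did not. Repeat content was not measured.

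The dense cover near the centromere was not due to 2L alone, since without 2L the ratio of percent covered was 1.27 (lowest and highest bound of both replicates 1.05 and 1.51); without 2L and 2R together the density ratio was 1.22 and was not called. The median score was lower in the proximal part in replicate 1 (1.07 against 1.25) and replicate 2 (1.10 against 1.30). Extra copies of proximal DNA that the score did not correct could raise cover, and were expected to raise the top scores as well. They could also let weaker regions into the list, which would lower its percentiles. The 90th percentile differed by -0.0326, proximal minus distal, with intervals of -0.10 to 0.02 and -0.09 to 0.00, so this explanation cannot be told apart from others. No biological explanation was tested.

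Scores on X were higher than on the autosomal arms, with a median difference of 0.13 (0.06 to 0.20) in replicate 1 and 0.11 (0.04 to 0.18) in replicate 2, but against 2R alone (-0.02 to 0.15) and 3R alone (-0.03 to 0.15) the interval of replicate 2 included 0. In the replicate-set list the median difference was 0.14 (0.03 to 0.24). There the intervals against 2L, 3L and 3R alone included 0, and that against 2R alone did not. Weak regions missing from X were considered as an explanation. The lists hold no counts, so whether X of these male cells had fewer reads than the autosomes could not be examined. Regions scored below 1 were fewer per Mb on X in replicate 1 (ratio 0.740, 0.614 to 0.880) and replicate 2 (0.736, 0.596 to 0.894). Those scored 1 and above had a mean ratio of 1.17, with lower bounds of 0.999 and 1.01. Regions of all scores together had density ratios of 0.992 (0.858 to 1.14) and 0.997 (0.864 to 1.15). At such near-equal density, higher scores on X would give this split whatever their cause. The split therefore cannot show that weak regions are missing. Among regions scored 1 and above the median score differed by 0.0306, X minus autosomes (lowest and highest bound -0.02 and 0.08). These regions were selected by the score itself, so this difference cannot tell missing weak regions from raised scores. The 90th percentile was higher on X by 0.13 (0.06 to 0.18) and 0.12 (0.02 to 0.16) in the replicates. In the replicate-set list it was higher by 0.056 (0.008 to 0.108). With autosomal weak regions weighted down to their share on X, the mean difference of the replicates was 0.0920. Its interval was 0.03 to 0.16 in replicate 1 and -0.01 to 0.13 in replicate 2. Whether missing weak regions are the whole cause therefore stays open. A uniform offset of X was expected to raise every percentile and the cover of X. The 10th percentile was higher on X by 0.19 on average, and the cover ratio of 0.941 had intervals that included 1. The lists hold only called regions, so an offset could also let weaker regions in and need not raise the low percentiles. These values therefore cannot tell an offset from the other explanations, and no biological explanation was tested.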
